A study of Rattus norvegicus with 9 samples.

How the data were processed

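The values were taken from the scanner files of Agilent 1-colour Cy3 rat arrays, in which the processed signal of each spot is an intensity after background subtraction, as deposited by the authors. The submitters' processing notes name Feature Extraction 9.1 and the file headers name Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09, and the plan written from the notes had named 9.1. RNA came from the amygdala of both sides of 1 rat per array, and 200 ng was labelled. Probe coordinates are those of rat build rn4 per the file headers. The scaling and filtering behind the authors' own value table are not given in the sources used here.

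Each array held 62976 spots. The 4259 control spots and spots marked as outliers by Feature Extraction were left out, and spots of the same probe were averaged, which gave 45598 probes. The signal was taken as log2 minus the 75th percentile of its array. In an alternative the background was corrected by normexp, with an offset of 50 added to the signal before log2. Such an offset by itself shrinks log2 differences of dim probes. Shifts of dim genes after normexp are therefore not by themselves evidence against a difference, and the part of the offset in them was not tested. A probe was tested if it was well above background on at least 4 of 9 arrays, which left 30215 probes, 30175 of them with complete values. Gene names came from the RefSeq accession of the probe (21184 probes), from its symbol (9060) or from a synonym (406), and 14948 probes were not matched. Of the matched probes 28188 carried a named gene, that is a symbol other than a predicted locus number or an accession. Whether a probe lies in a coding exon or an untranslated region is not given in the sources used here. Where a gene had several probes the brightest represented it.

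Groups were compared with limma 3.58.1 in R 4.3.3 (tables read with the package data.table in version 1.17.8), by lmFit and eBayes with group as the only term. P values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was called. Log2 differences are OV+E2 minus OV, and errors are standard errors of the fit unless SD is written. The word fell or rose is used for a result that passed a test, over all probes, over the fixed panel alone or over its list alone, and higher or lower for the rest. Where a gene was not well above background on any array of a group, the difference is printed as at least the fold between the other group and the signal at which spots become well above background, or the signal measured where that is higher.

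Gene lists were tested with camera at a preset correlation of 0.01 on 14988 named genes, with fry and with camera at an estimated correlation as alternatives. There were 17 pathway lists and 19 lists of cell type or region markers, adjusted together over 36. In all 2 written members were not matched to a gene. Adjusted over the list alone means Benjamini-Hochberg over the members of that list. The contrast, the lists, the panel of 24 genes, the filter, the thresholds and the rule for naming genes were fixed before the data were examined. That rule named the 14 genes of smallest p in each direction when none passed, up to 4 members of smallest p in each list, and the panel. Some members of the panel and of the lists are not reported here.

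The methods were tested on simulated data, in which 200 of 30175 probes were given a change. Each probe took its mean and residual SD from these arrays. Noise was drawn independently for each probe, with the same SD on every array. With 9 arrays 24% of changed probes were called at a 1.5-fold change, 56% at 2-fold, 70% at 3-fold and 88% at 4-fold, with 6 unchanged probes called. Without OV replicate 3 the shares were 56%, 74%, 82% and 86%, with 9 unchanged probes called. A list lowered 1.5-fold was called by camera with either correlation and by fry. With no list lowered camera at the preset correlation called 0 lists with 9 arrays and 1 without OV replicate 3. As simulated members varied independently, these list calls do not show what correlated members would give. The larger spread of OV replicate 3 was not simulated as that of 1 array. The number of arrays limits the precision of every difference printed here.

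The scanner files were used for all 9 arrays, with the authors' table as an alternative. That table holds 30469 probes with 321 empty cells, and 30000 of its probes pass the filter above. For OV replicate 3 the authors' column correlated at 0.939 with the scanner file of that rat, and at 0.984 to 0.994 with their other columns. OV replicate 3 was kept because it belonged to the plan, and each result was repeated without it.

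Replicate numbers were not used as pairs, as planned, and served as a block in an alternative. For numbers 1, 2, 3 and 5 the correlation of deviations between the groups was 0.170, −0.0761, −0.0110 and 0.105 in the scanner values, against up to 0.102 for other numbers. In the authors' values it was 0.122, −0.0121, 0.121 and 0.159, against up to 0.192. There numbers 3 and 5 lay above their own highest correlation with another number (0.0444 and 0.0193), so these values do not exclude a pairing. Slide was fitted as a block as an alternative. Slide 2 holds 1 OV array, and all arrays share 1 scan date, so no scan date was fitted.

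Array weights were first estimated gene by gene. After that result was seen REML on the probes with complete values took their place for speed. Both are reported, with the gene-by-gene weights as the planned setting. The weight of OV replicate 3 was 0.0498 by the former and 0.0489 by the latter. Of the 126 groupings of the arrays into 4 and 5, 100 were counted: the true one and 99 others drawn at random. All 40 groupings with as many OV arrays on each slide were counted with slide as a block, a test added after results were seen. An array was set apart by Dixon's ratio, with critical values of 0.829 for 4 arrays and 0.71 for 5.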

Results

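Amygdala RNA from 9 female spontaneously hypertensive rats (SHR, an inbred model of high blood pressure) was measured on 1-colour expression arrays, with 1 rat on each array. All rats were ovariectomised at 4 weeks of age. After 1 week of recovery 4 rats (OV) received a minipump with vehicle and 5 rats (OV+E2) a pump delivering 2 µg of estradiol a day, and tissue was taken 4 weeks later at 9 weeks of age. The 75th percentile of the signal lay between 556.8 and 737.6 on 8 arrays and was 129.7 on OV replicate 3. The same 8 arrays held 29052 to 31395 probes well above background, against 24225 on OV replicate 3. OV replicate 3 had a mean correlation of 0.932 with the other arrays, and the other 8 had means of 0.981 to 0.984. For that rat the authors' own value column differed from the scanner file: the SD of their log2 ratio was 1.00, against 0.00417 to 0.0308 for the other 8. The arrays sat on 2 slides, slide 1 with 5 arrays (OV replicates 1, 2 and 3, OV+E2 replicates 1 and 2) and slide 2 with 4 arrays (OV replicate 5, OV+E2 replicates 3, 4 and 5).

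Estradiol was set against vehicle in the amygdala of these ovariectomised rats. Genes of the interferon response and of antigen presentation fell as a group, with 19 of 23 members lower in OV+E2 and a median log2 change of −0.27 (adjusted p = 7.42e-08; adjusted p = 0.357 with an estimated correlation). Irf7, a transcription factor that drives type I interferon, was lower by a log2 difference of −0.90 (SE 0.13, n = 4 OV and 5 OV+E2). The vasopressin gene Avp fell by 1.08 (SE 0.24, n = 4 and 5) within the panel of genes fixed beforehand, a call that was lost with slide as a block. S100g, which encodes the calcium-binding protein calbindin-D9k, was higher by +1.59 (SE 0.20, n = 4 and 5) without passing over all probes. After background correction by normexp, with its offset of 50, this dim gene was at +0.0626. The signal of 8 of these genes in each rat is shown with the group means and SDs.

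**Figure D1:**
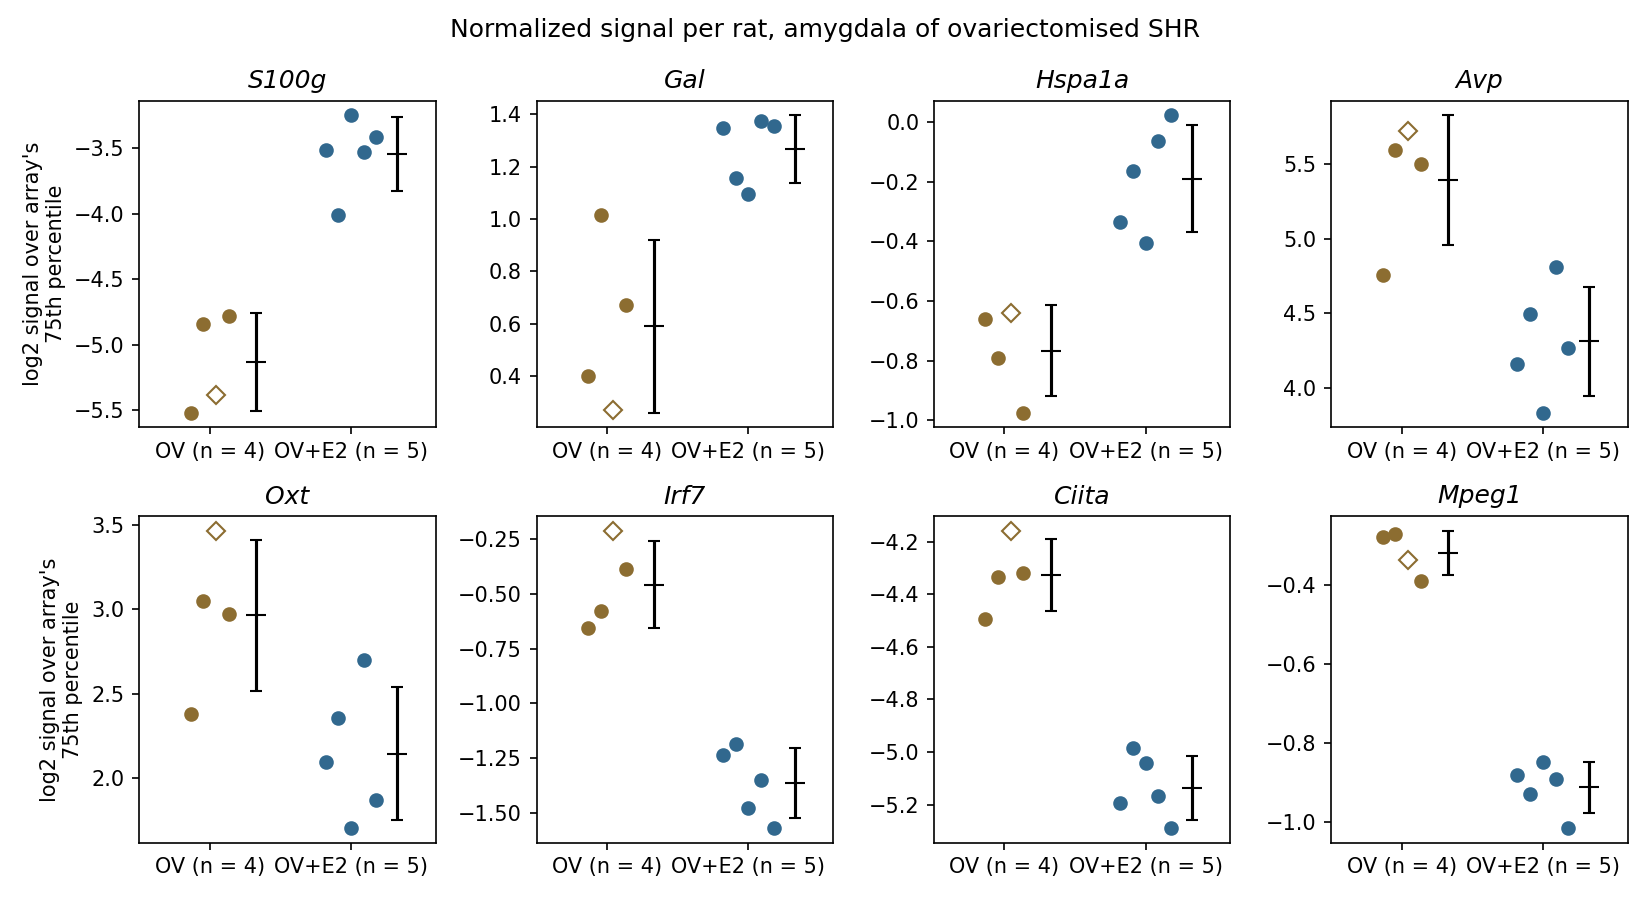
Normalized signal of 8 genes (log2 of the signal over the 75th percentile of the array) in 4 OV rats (brown, OV replicate 3 as an open diamond) and 5 OV+E2 rats (blue), with the group mean and SD beside the points. Avp has means of 5.39 in OV and 4.31 in OV+E2, and S100g of −5.13 and −3.54.

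No probe passed an adjusted p of 0.05 in limma: 0 of 30215 tested, with a smallest adjusted p of 0.156. At an unadjusted p under 0.05 there were 3136 probes, 969 higher and 2167 lower in OV+E2. Under an unadjusted p of 0.01 with at least a 1.5-fold difference 653 probes remained, 85 higher and 568 lower. Over 99 other groupings of the 9 arrays that looser count had a median of 34 and a highest value of 509. With slide as a block the counts were 0 and 431 (64 higher, 367 lower), and of 39 other groupings with as many OV arrays on each slide 1 gave a higher looser count, 474. The authors' processed values gave 69 probes at the adjusted threshold (23 higher, 46 lower) and limma's array weights gave 1300 (339 higher, 961 lower), counts that became 1 and 4 without OV replicate 3. The count in the authors' values also became 0 to 1381 with each other array left out. In the planned fit without OV replicate 3 a single probe without a gene name passed, higher by 1.64 (SE 0.13, adjusted p = 0.0461). Without OV replicate 1 a single gene passed, Defb42, lower by −1.15 (adjusted p = 0.0495). The looser count split into 130 higher and 413 lower after quantile normalization, and 147 higher and 466 lower after median scaling. It was 7 higher and 215 lower after background correction by normexp, 89 and 1063 without the filter on dim probes, and 21 and 372 with probes well above background on all 9 arrays. Median scaling moved the median of all probes from 0.00 to +0.11, normexp to −0.11, and dropping the filter to −0.13.

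Among the 14 genes of smallest p on the higher side none passed adjustment over all probes. S100g had the smallest adjusted p of them, 0.197, with means of −5.13 in OV and −3.54 in OV+E2 on the log2 scale. Its probe, at 52449257 to 52449316 on chromosome X of rn4, was well above background on 1 of 4 OV arrays and 5 of 5 OV+E2 arrays. The difference for S100g was +1.48 within slide 1, +1.38 within slide 2 and +1.44 with slide as a block, and it passed in the authors' values (+1.64, adjusted p = 0.0350) but not in these without OV replicate 3 (adjusted p = 0.119). Gpihbp1, which anchors lipoprotein lipase to capillary endothelium, was well above background on 0 of 4 OV arrays and was higher by at least 1.54-fold, but lower after normexp (−0.17). Normexp also left S100g at +0.0626, Il23a at +0.0369 and Serpina1 at +0.0243. Of the genes named below it left Nt5dc3 at +0.13, Lin9 at +0.17, Lgr6 and Ctnnal1 at +0.21 each, Slc6a5 at +0.26, Styk1 at +0.28 and Acer2 at +0.40. Sult1a1, a sulfotransferase of phenols and steroids, was higher by +0.65 (SE 0.11). Slc6a5, the neuronal glycine transporter, was higher by +0.86 (SE 0.16), and both passed in the authors' values with adjusted p of 0.0428 and 0.0350. These calls were lost with slide as a block (0.0823 and 0.0659) and without OV replicate 3 (0.139 and 0.120). The efflux transporter Abcg2 was higher by +0.49, the inducible Hsp70 gene Hspa1a by +0.58 and the R-spondin receptor Lgr6 by +0.75. The others were Styk1 (+0.77), Ctnnal1 (+0.78), Nt5dc3 (+0.67), Serpina1 (+0.61), Acer2 (+0.60), Il23a (+0.54) and Lin9 (+0.39). A second probe of Nt5dc3 ran the other way, at −0.55.

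None of the 14 genes of smallest p on the lower side passed adjustment over all probes either. Defb42, a beta-defensin gene, had the smallest adjusted p of all probes (−1.06, SE 0.11, adjusted p = 0.156; chromosome 15, 42247668 to 42247727). Ciita, the transactivator of MHC class II genes, was lower by −0.81 (SE 0.10; chromosome 10, 5086386 to 5086445). Mpeg1, a macrophage gene for perforin-2, was lower by −0.59 (SE 0.08; chromosome 1, 215391680 to 215391739). For Irf7 (chromosome 1, 201456889 to 201456948) the difference was −0.73 within slide 1, −1.08 within slide 2 and −0.86 with slide as a block. Ciita, Mpeg1, Irf7 and Defb42 all passed in the authors' values, with adjusted p of 0.0188, 0.0275, 0.0468 and 0.0188. With slide as a block on those values Mpeg1 (0.0533) and Irf7 (0.102) lost the call, and without OV replicate 3 Ciita, Mpeg1 and Defb42 (0.0861 each) and Irf7 (0.0962) did.

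Further lower genes coded for transporters and enzymes: the sterol transporter subunit Abcg8 (−0.98), the sulfotransferase Sult1c2 (−1.37), the aldo-keto reductase Akr1c13 (−0.77), the muscle phosphoglycerate mutase Pgam2 (−0.91) and Sdr42e2 (−1.11). The cold- and menthol-gated channel Trpm8 was lower by −1.72 (SE 0.30) and the olfactory receptor gene Or4a77 by −1.88 (SE 0.33). Or4a77 was well above background on 3 of 4 OV and 2 of 5 OV+E2 arrays. Krt87 (−1.17), Spata31d3 (−0.71) and Apobec2 (−0.45) completed the list. After normexp Or4a77 was at −0.92, Krt87 at −0.73, Sult1c2 and Sdr42e2 at −0.72 each and Defb42 at −0.69. All 28 genes had the same direction in the authors' values and without OV replicate 3. That was nearly fixed in advance, as the genes were picked by p on these arrays. Both checks reuse every array but OV replicate 3. In the authors' values 12 of the 28 passed. Of these, 4 kept the call with slide as a block on those values, where Abcg2 gained one (adjusted p = 0.0462), and without OV replicate 3 none of the 28 passed.

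The fixed panel named 24 genes of oestrogen action, amygdala neuropeptides, pituitary hormones and blood pressure, and 20 were bright enough to test. Not tested were Esr2 (well above background on 1 array), Cyp19a1 (2 arrays), Prl and Gh1 (0 arrays each). Avp was the only member to pass adjusted over the panel alone: it fell by 1.08 (SE 0.24, panel-alone adjusted p = 0.0320), from 5.39 (SD 0.43) in OV to 4.31 (SD 0.36) in OV+E2. Over all probes its adjusted p was 0.251. The Avp probe lies on chromosome 3 at 118205082 to 118205141, and the difference was −1.03 within slide 1, −1.19 within slide 2 and −1.09 with slide as a block. With slide as a block the panel call for Avp was lost (panel-alone adjusted p = 0.0842), and so it was with replicate number as a block (0.0644). It was also lost without OV replicates 2, 3 and 5 (panel-alone adjusted p = 0.123, 0.0855 and 0.115) and without OV+E2 replicates 1, 2, 3 and 5 (0.0939, 0.0599, 0.0760 and 0.0877). The neighbouring oxytocin gene Oxt was lower by −0.82 (SE 0.26, panel-alone adjusted p = 0.107), with −1.07 for its second probe. Oxt passed over the panel alone without OV replicate 1 (−1.01, panel-alone adjusted p = 0.0269) and without OV+E2 replicate 4 (−0.96, panel-alone adjusted p = 0.0416). Th, which encodes the rate-limiting enzyme of catecholamine synthesis, was lower by −0.61 (SE 0.27; panel-alone adjusted p = 0.258).

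The oestrogen and progesterone receptor genes of the panel did not pass: Esr1 −0.07 (SE 0.19), Gper1 −0.21 (SE 0.21; +0.11 on its second probe) and Pgr +0.29 (SE 0.21). Without OV replicate 3 Esr1 was at −0.28, and in the authors' values it fell by 0.29 (panel-alone adjusted p = 0.0482). The oestrogen-induced gene Greb1 was at +0.18 (SE 0.14), with −0.10 to +0.33 over its 4 probes, +0.32 without OV replicate 3 and +0.04 after normexp. The oxytocin receptor gene Oxtr was higher by +0.67 (SE 0.27) on 1 probe, which was at +0.37 without OV replicate 3 and −0.22 after normexp, and lower by −0.43 on the other. Peptide genes lay near 0: Npy +0.05, Crh +0.05, Cartpt +0.05, Tac1 +0.04, Penk +0.01 (−0.21 on its second probe) and Cck −0.03, with Trh at +0.20 (SE 0.41). The peptide receptor genes Avpr1a and Crhr1 were at +0.09 and −0.03 (+0.46 on the second probe of Crhr1), and of the angiotensin genes Agtr1a was at +0.14 and Agt at −0.26 (−0.06 without OV replicate 3, −0.05 in the authors' values). Several of these went opposite ways within slides 1 and 2: Npy −0.17 and +0.35, Crh −0.18 and +0.41, Tac1 −0.37 and +0.53, Penk −0.26 and +0.25, Avpr1a +0.37 and −0.33. The direction of Agtr1a, Avpr1a, Gper1, Cartpt, Penk and Cck turned without OV replicate 3 (−0.18, −0.24, +0.04, −0.09, −0.10 and 0.00).

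Of 36 gene lists 8 shifted in limma's camera test with its preset correlation, 6 down and 2 up. Over 99 other groupings of the 9 arrays this count had a median of 4 and a highest value of 10. With slide as a block it was 5, against a median of 3 over 39 other groupings. With the correlation estimated for each list 0 of 36 passed, and with fry 1 did, the interferon list. No member of any list passed adjustment over all probes. The interferon and antigen presentation list (23 members) had 7 that fell adjusted over the list alone and 16 not passing. These were Irf7 (list-alone adjusted p = 0.00120), the immunoproteasome subunit Psmb9 (−0.51, list-alone adjusted p = 0.00614), the antiviral Rsad2 (−0.58, list-alone adjusted p = 0.00730), Isg15 (−0.64), the MHC class II invariant chain Cd74 (−0.57), Gbp2 (−0.40) and Irf9 (−0.30). The median of the list was −0.24 within slide 1 and −0.47 within slide 2, and with slide as a block the adjusted p was 7.75e-08. The fry test gave an adjusted p of 0.0228, but 0.0847 without OV replicate 3 and 0.149 in the authors' values. The list fell in the authors' values too (adjusted p = 5.71e-07, 9 members fell list alone; adjusted p = 0.655 with an estimated correlation) and without OV replicate 3 (adjusted p = 9.67e-10; adjusted p = 0.383 with an estimated correlation). In camera at the preset correlation it held when any other array was left out. Many other groupings of the arrays also gave this list an adjusted p under 0.05 in that test. Such a p by itself therefore does not exclude chance here. The lowest of them was 8.47e-08, from OV+E2 replicates 2, 3, 4 and 5 against the rest. That grouping differs from the true one only in the place of OV+E2 replicate 1. With slide as a block the lowest of another grouping was 4.65e-05. The members of the 8 shifted lists, of the neuropeptides and of the oestrogen list are drawn side by side.

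**Figure D2:**
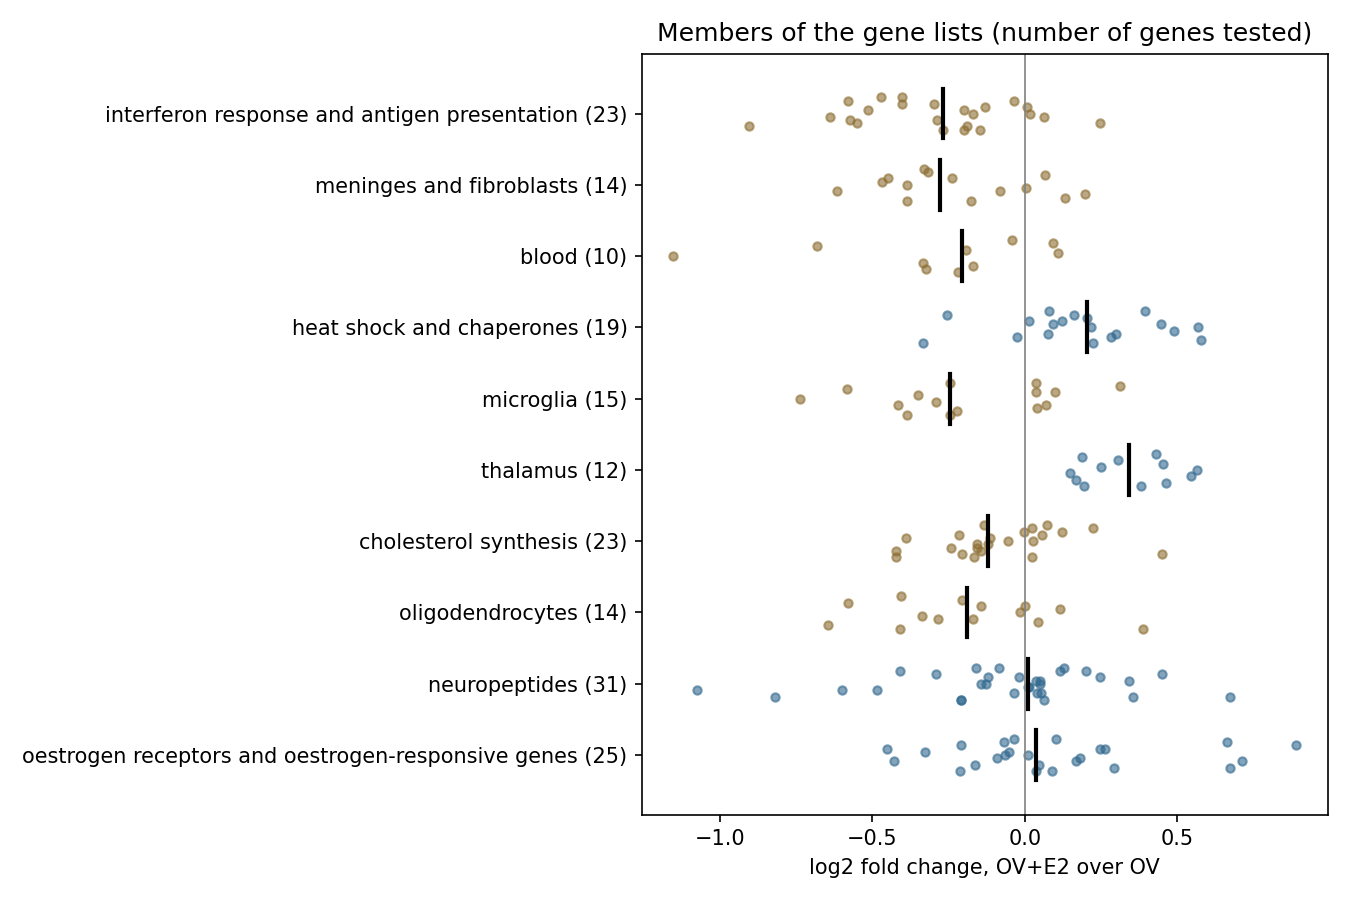
Log2 difference, OV+E2 minus OV, of each member (point) of 10 gene lists, with a bar at the median and blue for a median above 0, brown below. In the interferon list 19 of 23 members lie below 0, and in the thalamus list 12 of 12 lie above.

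The lists of microglia and blood markers fell beside that list, each with members in both directions. Red-cell genes are among the blood markers. Microglia markers (15 members, 9 lower) fell with a median of −0.25 (adjusted p = 0.0245; adjusted p = 0.528 with an estimated correlation). The integrin subunit gene Itgam fell list alone (−0.58, list-alone adjusted p = 0.00740), and 14 members were not passing, with Aif1 at −0.39, Cd68 at −0.35 and Cx3cr1 at −0.74. Of the microglia markers 5 lower and 1 higher had an unadjusted p under 0.05 in limma. The median of the microglia markers was −0.20 within slide 1 and −0.13 within slide 2, with an adjusted p of 0.0655 with slide as a block. The call was lost without OV replicate 1 (adjusted p = 0.169) and without OV+E2 replicate 3 (adjusted p = 0.0515). It was also lost after normexp (0.0626), without the filter on dim probes (0.139) and over the mean of probes (0.108), and the median was −0.19 without OV replicate 3 and −0.16 in the authors' values. List alone 3 microglia members fell without OV replicate 3, and 4 in the authors' values. Blood genes (10 members, 8 lower) fell with a median of −0.21 (adjusted p = 0.00517; adjusted p = 0.528 with an estimated correlation). Of these the neutrophil gene S100a8 fell list alone (−1.15, list-alone adjusted p = 0.0363), while 9 were not passing, among them the red-cell genes Slc4a1 (−0.68), Hba-a1 (−0.33) and Ahsp (−0.22). The blood median was −0.18 within slide 1 and −0.41 within slide 2, the adjusted p with slide as a block was 0.00180, and the authors' values gave 0.0668 with a median of −0.14 and S100a8 at −0.61. With probes well above background on all 9 arrays the adjusted p was 0.0659, and without OV replicate 3 the median was −0.31. Without that array 6 blood members fell list alone, and 0 did in the authors' values. Endothelial markers (14 members) had a median of −0.13 (adjusted p = 0.258), with Slco1a4 at −0.37 and Vwf at −0.60 and 0 members passing. They fell without OV replicate 3 (adjusted p = 0.0253; adjusted p = 0.540 with an estimated correlation) and in the authors' values (adjusted p = 0.0405; adjusted p = 0.655 with an estimated correlation).

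Genes of the meninges and fibroblasts (14 members, 10 lower) fell with a median of −0.28 (adjusted p = 0.00282; adjusted p = 0.528 with an estimated correlation). The fibrillar collagen genes Col1a1 (−0.62, list-alone adjusted p = 0.00599) and Col3a1 (−0.47, list-alone adjusted p = 0.0202) fell list alone and 12 members were not passing, with Col1a2 at −0.33. The median was −0.30 within slide 1 and −0.28 within slide 2, with an adjusted p of 0.000176 with slide as a block. It was −0.18 without OV replicate 3 and −0.12 in the authors' values. The call was lost without OV replicate 5 (adjusted p = 0.0536). Pericyte and smooth muscle markers (10 members) had a median of −0.08 (adjusted p = 0.514), 0 passing, with Des at −0.61.

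Heat shock and chaperone genes (19 members, 16 higher) rose with a median of +0.20 (adjusted p = 0.0224; adjusted p = 0.528 with an estimated correlation). Hspa1a rose list alone (list-alone adjusted p = 0.0205) and 18 members were not passing, among them the endoplasmic reticulum chaperone Hspa5 (+0.49) and Dnajb1 (+0.40). Both without OV replicate 3 and in the authors' values 3 members rose list alone. The median was +0.20 within slide 1 and +0.29 within slide 2, with an adjusted p of 0.00180 with slide as a block. Without OV replicate 5 the call was lost (adjusted p = 0.0902), and without OV replicate 3 the median was +0.16. Genes of cholesterol synthesis (23 members, 15 lower) fell with a median of −0.12 (adjusted p = 0.0403; adjusted p = 0.528 with an estimated correlation). No member passed list alone, with Tm7sf2 at −0.42, Mvk at −0.42 and Mvd at −0.39. Their median was −0.07 within slide 1 and −0.08 within slide 2, and the adjusted p with slide as a block was 0.0709. The cholesterol call was lost without OV replicates 1, 2 and 5 (adjusted p = 0.242, 0.198 and 0.0731) and without OV+E2 replicates 3, 4 and 5 (0.0703, 0.0912 and 0.0542). Median scaling left the cholesterol median at −0.01 (adjusted p = 0.150) and normexp at −0.03 (adjusted p = 0.374). The call was lost too with replicate number as a block (0.170), without the filter on dim probes (0.185), with probes well above background on all 9 arrays (0.0690) and over the mean of probes (0.157).

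Markers of oligodendrocytes (14 members, 10 lower) fell with a median of −0.19 (adjusted p = 0.0403; adjusted p = 0.752 with an estimated correlation). No member passed list alone, and the myelin genes Mbp, Mobp and Mog were at −0.65, −0.58 and −0.34. With 1 array left out they ranged from −0.82 to −0.28, −0.83 to −0.35 and −0.44 to −0.25. The median was −0.01 within slide 1 and −0.26 within slide 2, with an adjusted p of 0.308 with slide as a block. The oligodendrocyte call was lost without OV replicates 1, 2 and 5 (adjusted p = 0.121, 0.0732 and 0.0902) and without OV+E2 replicates 3, 4 and 5 (0.169, 0.106 and 0.0902). It was lost too after quantile normalization (0.0570, median −0.06) and normexp (0.198), with replicate number as a block (0.195), without the filter on dim probes (0.183), with probes well above background on all 9 arrays (0.0532) and over the mean of probes (0.226). Without OV replicate 3 the median was −0.12. Oligodendrocyte precursors (8 members) had a median of −0.04 (adjusted p = 0.514), 0 passing, with Gpr17 at −0.89. Astrocyte markers (13 members) had a median of −0.01 (adjusted p = 0.577), 0 passing, with Gjb6 at +0.18 and Slc1a2 at −0.46. Neuronal markers (14 members) had a median of +0.11 (adjusted p = 0.449), 0 passing, with Eno2 at +0.21 and Nefl at −0.28. Ependymal markers (9 members) were at +0.08 (adjusted p = 0.975), 0 passing, with Rarres2 at −0.17. Choroid plexus markers (15 members, 14 higher) had a median of +0.27 (adjusted p = 0.449), 0 passing, with Sostdc1 at +1.36 and Otx2 at +0.81. Their median was +0.63 within slide 1 and −0.06 within slide 2, and +0.60 without OV replicate 3. They rose with array weights (adjusted p = 0.00255; adjusted p = 0.735 with an estimated correlation). Their score was −1.20 in OV replicate 2 and +1.34 in OV+E2 replicate 2, and Dixon's ratio was not taken for this list.

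Markers of neighbouring regions bear on where the tissue was dissected. Thalamus markers (12 members, 12 higher) rose with a median of +0.34 (adjusted p = 0.0385; adjusted p = 0.752 with an estimated correlation). No member passed list alone; Ramp3 was at +0.57, Rora at +0.46 and Slc17a6 at +0.31. The thalamus median was +0.76 within slide 1 and −0.04 within slide 2, with an adjusted p of 9.96e-05 with slide as a block and 0.193 in the authors' values. The call was lost without OV replicates 1, 2, 3 and 5 (adjusted p = 0.139, 0.0692, 0.169 and 0.0654), with medians of +0.34, +0.41, +0.29 and +0.36. It was also lost without OV+E2 replicates 1 and 2 (adjusted p = 0.102 and 0.265), with medians of +0.28 and +0.17. It was lost too after quantile normalization (0.0682), median scaling (0.0926) and normexp (0.123), without the filter on dim probes (0.0527), with probes well above background on all 9 arrays (0.0659), over the mean of probes (0.108) and with array weights (0.416, median +0.14). Striatum markers (16 members) had a median of −0.17 (adjusted p = 0.0709), 0 passing, with Gng7 at −0.74 and Drd2 at −0.37. Their median was −0.38 within slide 1 and +0.28 within slide 2, with an adjusted p of 0.0655 with slide as a block, and −0.10 without OV replicate 3. The striatum score was 2.53 in OV+E2 replicate 1, against 3.15 to 3.42 in the other OV+E2 rats. They fell without OV replicate 5 (adjusted p = 0.0214) and without OV+E2 replicates 2, 3 and 4 (0.0343, 0.0494 and 0.0139), where an estimated correlation gave an adjusted p of 0.688 or more. They also fell after quantile normalization (0.0483; 0.772 with an estimated correlation), median scaling (0.0423; 0.948 with an estimated correlation) and with replicate number as a block (0.00331; 0.772 with an estimated correlation). Cortex markers (15 members) were at +0.11 (adjusted p = 0.514) and hippocampus markers (11 members) at −0.08 (adjusted p = 0.546), with 0 passing in either and Slc17a7 at +0.30 and Wfs1 at +0.38.

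Hypothalamus markers (13 members) had a median of −0.17 (adjusted p = 0.258; adjusted p = 0.0488 after normexp, where an estimated correlation gave 0.806), yet 5 members passed list alone. Avp (list-alone adjusted p = 0.0125), Oxt (list-alone adjusted p = 0.0319) and Pomc (−0.49, list-alone adjusted p = 0.0319) fell, while the galanin gene Gal (+0.68, SE 0.16, list-alone adjusted p = 0.0125) and Asb4 (+0.55, list-alone adjusted p = 0.0242) rose, with Asb4 at −0.05 after normexp. Markers of the medial amygdala (13 members), where Avp and Gal neurons also lie, had a median of −0.04 (adjusted p = 0.577), with Avp fallen and Gal risen list alone and 11 not passing. Central amygdala markers (16 members) were at +0.05 (adjusted p = 0.975), 0 passing, with Pdyn at −0.29 and Prkcd at +0.85. Basolateral amygdala markers (13 members) were at +0.11 (adjusted p = 0.577), 0 passing, with Lmo3 at +0.25. In the neuropeptide list (31 members, median +0.01, adjusted p = 0.514) Avp fell and Gal rose list alone (list-alone adjusted p = 0.0299 each) and 29 were not passing, among them Nmu (−0.60, list-alone adjusted p = 0.0507). Without OV replicate 3, 0 members of that list passed list alone. In the authors' values 1 rose and 3 fell. Lists were adjusted 1 by 1, so Avp and Gal count anew in each list that holds them. Neuropeptide and hormone receptors (37 members) had a median of +0.09 (adjusted p = 0.436), 0 passing, with Ghr at +0.20, Npy2r at +0.35 and Prlr at +0.89.

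The list of oestrogen receptors and oestrogen-responsive genes (25 members) had a median of +0.04 (adjusted p = 0.514). Gal rose list alone (list-alone adjusted p = 0.0482) and 24 were not passing, with Igf1r at +0.26. Without OV replicate 3, 5 members of this list rose list alone. In the authors' values 4 rose and 1 fell. In steroid synthesis and metabolism (17 members, median +0.09, adjusted p = 0.449) Sult1a1 rose list alone (list-alone adjusted p = 0.00292) and 16 were not passing, among them the brain cholesterol hydroxylase Cyp46a1 (+0.57). Members of that list risen list alone were 2 without OV replicate 3 and 2 in the authors' values. The renin-angiotensin and blood-pressure list (32 members) had a median of +0.03 (adjusted p = 0.975), 0 passing, with Edn3 at −0.41 and the angiotensin-(1-7) receptor gene Mas1 at +0.50. Inflammation and complement genes (24 members, median +0.04, adjusted p = 0.543) had 22 not passing and 2 that fell list alone, Serping1 (−0.42, list-alone adjusted p = 0.0479) and Tlr2 (−0.39, list-alone adjusted p = 0.0489).

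Lists of transmitter systems and cell activity did not pass in the planned test. Glutamate signalling (36 members) was at +0.04 (adjusted p = 0.975), 0 passing, with Grin2d at −1.33 (SE 0.33) and Gria1 at −0.36. GABA signalling (22 members) was at −0.02 (adjusted p = 0.546), 0 passing, with Gabrq at −0.39. Monoamine and acetylcholine signalling (29 members) was at −0.02 (adjusted p = 0.449), 0 passing, with Ddc at −0.38 and Drd5 at −0.78, and it fell in the authors' values (adjusted p = 0.0405; adjusted p = 0.655 with an estimated correlation). Synaptic vesicle and plasticity genes (34 members) were at +0.06 (adjusted p = 0.449), 0 passing, with Syp at +0.47 and Ntrk2 at +0.24, and they rose after normexp (adjusted p = 0.0160; adjusted p = 0.806 with an estimated correlation). Immediate early genes (24 members) were at 0.00 (adjusted p = 0.975), 0 passing, with Dusp1 at +0.55 and Jun at +0.19. Growth factor genes (31 members) were at +0.01 (adjusted p = 0.577), with 0 passing. Oxidative phosphorylation (45 members) was at −0.04 (adjusted p = 0.514), 0 passing, with Cox8a at −0.25 and Ndufs8 at +0.31. Thyroid hormone and retinoid handling (20 members) was at −0.07 (adjusted p = 0.514), 0 passing, with Hr at −0.68 and Dio2 at +0.35.

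Median, mean and test differed in sign for 8 lists that did not shift. The test ran down with a median above 0 for the neuropeptides, inflammation and complement, growth factors, immediate early genes, renin-angiotensin and central amygdala lists. In the last 2 the mean was above 0 too (+0.05 for each). Oxidative phosphorylation ran down with a mean of +0.01, and glutamate signalling ran up with a mean of −0.03. Medians of further lists that did not shift went opposite ways within slides 1 and 2: immediate early genes −0.29 and +0.32, neuropeptides −0.18 and +0.14, central amygdala −0.17 and +0.21. Without OV replicate 3 the basolateral amygdala median was −0.03 and the monoamine and acetylcholine median −0.12.

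Many example genes of the lists also moved when OV replicate 3 was left out. Lower genes closer to 0 were Gpr17 (−0.44), Slc1a2 (−0.18), Slc4a1 (−0.43), Drd2 (−0.17), Gng7 (−0.40), Vwf (−0.32), Des (−0.39), Rarres2 (−0.02), Cd68 (−0.21), Cx3cr1 (−0.47), Tm7sf2 (−0.28), Mvd (−0.23) and Mvk (−0.25). Higher genes closer to 0 were Hspa5 (+0.31), Wfs1 (+0.03), Lmo3 (+0.13), Npy2r (+0.22), Ndufs8 (+0.15), Mas1 (+0.32), Cyp46a1 (+0.31), Ramp3 (+0.38) and Dio2 (+0.20).

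OV replicate 3 differs from the other arrays and slide 2 holds 1 OV array, so each OV mean rests on 4 rats of which 1 is in doubt. In simulated data of this size, with the same noise level on every array, a 2-fold change was called for 56% of changed probes.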

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

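The search for single arrays that stand apart was planned, and the tests of the causes of the patterns below were chosen after results were seen, except the test of dim spots and the counts over other groupings, of which those with array weights and those with slide as a block were chosen after. In each group of arrays the furthest value was compared with its nearest neighbour by Dixon's ratio. Of 138 such groups 15 were set apart, where a chance of about 1 in 20 for each would give several. OV replicate 3 accounts for 7 of the 15.

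The spike-in controls had a median net signal of 1452 on OV+E2 replicate 2, against 726.1 to 778.9 on the other OV+E2 arrays, while its 75th percentile of sample signal was 622.9. OV replicate 3 had a mean correlation of 0.932 with the other arrays. Its blood score in the authors' values was 8.79 (other OV rats 9.52 to 9.59), and its thalamus score in the scanner values was −0.53 (other OV rats −0.26 to −0.24). Among genes on OV replicate 3, Slc6a5 stood at −3.23, Esr1 at −3.31 and Greb1 at −1.14, and Gper1 at 0.55. On other arrays Spata31d3 was −1.80 on OV replicate 1, Pgr −3.31 on OV replicate 5 and −2.03 on OV+E2 replicate 2. Oxtr was −4.57 and Cartpt 0.23 on OV+E2 replicate 2. Npy was 4.36 and Tac1 3.91 on OV+E2 replicate 1, each below the other OV+E2 rats.

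The scanner file and the authors' column of OV replicate 3 hold different values. A single rescaling would keep the order of probes, and Spearman's rho was 0.930 over 30207 probes, which argues against it. Noise of dim spots is argued against by the brightest probes, where the SD of the log2 ratio was 0.811 against 0.0258 in the other rats. The authors' column correlated at 0.984 or more with every other rat's file and at 0.939 with its own, which is consistent with a column from another hybridisation than the file. That both hold RNA of the same rat and that they do not cannot be told apart: deviations over the 500 most variable probes correlated at 0.279 with its own column and at 0.260 with that of OV replicate 5, under a margin tightened after the result was seen.

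Interferon and antigen presentation genes were lower in OV+E2, and 3 causes other than a response of the cells were tested. A smaller share of microglia cannot be told apart, as microglia markers had a median of −0.246 (95% bootstrap interval −0.351 to 0.0418). The bootstrap here and for the hypothalamus markers below drew genes of a list, not rats, so its intervals hold no error between rats. Less blood in the tissue may contribute, with a median of −0.206 for blood genes (−0.504 to −0.0383). The file of OV replicate 3 is argued against, since the median without it was −0.259 against −0.270 with it.

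Avp and Oxt were lower together, and both are abundant in the hypothalamus beside the amygdala. A level of −0.409, taken from the change of Oxt itself, was set for less hypothalamic tissue. The other 11 hypothalamus markers had a median of −0.0380 (−0.209 to 0.201). Their members go both ways, from Pomc at −0.485 to Gal at +0.676, so that cause cannot be told apart, under a bar raised after the result was seen. The mean of Avp and Oxt without OV replicate 3 was −0.810 against −0.948 with it, which argues against that array as the whole cause of the lower values.

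Other groupings of the arrays were counted to see whether chance can be excluded. Each number of groupings includes the true one. For probes at the adjusted threshold the count cannot tell, since every grouping reaches the true count of 0; the highest other count was 1. For the looser count without slide in the model 1 of 100 was as large, the true grouping itself with 653. The highest other was 509. That 509 came from OV replicates 1 and 2 with OV+E2 replicates 1 and 2, which is slide 1 without OV replicate 3. Over the 40 groupings with as many OV arrays on each slide, and slide as a block, chance cannot be excluded for the looser count: the true count was 431, 2 of 40 were as large and the highest other was 474.

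For gene lists without slide in the model the share was just under 1 in 20, with 4 of 100 as large. The true count was 8 and the highest other was 10. Only 100 of the 126 groupings were counted, so the full share could lie on either side of 1 in 20. Chance cannot be excluded for the lists with slide as a block, with a true count of 5, 12 of 40 as large and a highest other of 12. With an estimated correlation 0 lists shifted. In the authors' values 3 of 100 were as large as the true count of 69. The highest other was 251, from the same grouping that follows slide 1. With slide as a block on those values 1 of 40 was as large as the true count of 26, the true grouping itself. The highest other was 2. A share of 1 of 40 is the smallest these groupings can give, and this test was chosen after results were seen. With array weights by REML and no slide in the model, 2 of 100 groupings reached the true count of 3506, under 1 in 20. The highest other was 10618, from OV replicates 2, 3 and 5 with OV+E2 replicate 2, which mixes the slides. The count with REML weights was not repeated with slide as a block, which raised the share for the looser count and the lists. The shares were not corrected for the number of such tests. Chance is therefore not called excluded for any of these counts. The count of 69 in the authors' values and that of 3506 both depend on single arrays. The 69 became 1 without OV replicate 3, 0 to 29 without 6 of the other arrays, 78 without OV+E2 replicate 2 and 1381 without OV replicate 1, so its fall is not specific to the array in doubt. The 3506 became 16 without OV replicate 3 and 478 to 14693 without each other array. The grouping with 251 follows slide 1. That with 10618 is the true one with OV replicate 1 and OV+E2 replicate 2 swapped. Why these counts exceed those of the true grouping was not tested.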

How the results depend on the processing

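The slide block without OV replicate 3, the authors' values with a slide block, without OV replicate 3, with each other array left out or over all their probes, and all array weights by REML or with another alternative were tests chosen after results were seen. The other settings were planned. Of 84 genes followed, 12 kept direction and side everywhere, 18 turned direction in some setting and 55 were called in some. The cause was not tested for any of these shifts. Scan date was not run as a block because all arrays have 1 scan date.

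Probes at the adjusted threshold (0) and under the looser rule (653) were 69 and 948 in the authors' values, 26 and 802 with their values and a slide block, 1 and 597 with their values without OV replicate 3, and 114 and 1062 over all probes of their table. Array weights gave 1300 and 1250, by REML 3506 and 1511. Without OV replicate 3 the weights gave 4 and 977, by REML 16 and 1003. The authors' values with 1 other array left out gave 1381 and 1319 (OV replicate 1), 14 and 939 (OV 2), 12 and 644 (OV 5), 29 and 1084 (OV+E2 1), 78 and 1079 (OV+E2 2), 0 and 737 (OV+E2 3), 1 and 726 (OV+E2 4), 3 and 710 (OV+E2 5). Weights by REML in the same order gave 13014 and 2144, 2294 and 1838, 14693 and 2231, 4650 and 1920, 4938 and 1789, 1577 and 1299, 1076 and 1214, 478 and 1029. On the authors' values weights gave 2363 and 1488, by REML 2694 and 1551. No filter gave 9 and 1152, the filter on all 9 arrays 0 and 393, normexp 0 and 222, slide block 0 and 431, replicate block (pairing by number) 0 and 247. Genes as the mean over probes gave 1. Leaving out 1 array gave 0 to 1 and 402 to 1162.

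Panel genes passing panel alone (1) were 2 in the authors' values and with their slide block, 0 with their values without OV replicate 3, 0 with a slide block with or without OV replicate 3, 0 with the replicate block, 5 with array weights and 5 by REML. The 28 named genes passing over all probes (0) were 12 in the authors' values, 5 with their slide block, 0 with their values without OV replicate 3, and 28 with array weights and by REML. Lists shifted (8) were 0 with an estimated correlation, 1 with fry, 4 over the mean of probes, 4 with no filter, 4 with the filter on all 9 arrays and 5 with a slide block. Leaving out 1 array gave 0 to 2 panel genes, 0 to 1 named genes and 4 to 8 lists: 4 without OV replicate 1, 5 without OV replicate 2 and 4 without OV replicate 5.

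Log2 differences that turned sign, by setting. Quantile normalization: Esr1 0.0474, Crhr1 0.0204, Cck 0.21. Median scaling: Esr1 0.0373, Crhr1 0.0792, Cck 0.0710. Normexp: Gpihbp1 −0.17, Pgr −0.0910, Oxtr −0.22, Avpr1a −0.39, Cck 0.0733, Trh −0.0588, Agtr1a −0.32, Asb4 −0.0460, Grid2ip −0.20. Authors' values: Gper1 0.0591, Avpr1a −0.22, Penk −0.0747, Cck 0.0428, Cartpt −0.10, Agtr1a −0.22. Their slide block: Gper1 0.0617, Avpr1a −0.16, Penk −0.14, Cck 0.11, Tac1 −0.0206, Cartpt −0.15, Agt 0.0250, Agtr1a −0.27. Their values without OV replicate 3: Gper1 0.0401, Avpr1a −0.24, Penk −0.0949, Cck 0.00859, Cartpt −0.0906, Agtr1a −0.18. Array weights: Gper1 0.0562, Avpr1a −0.17, Crhr1 0.0667, Cartpt −0.0788, Trh −0.26, Agtr1a −0.32. By REML: Gper1 0.0642, Avpr1a −0.14, Crh −0.00726, Crhr1 0.0880, Cartpt −0.0913, Trh −0.37, Agtr1a −0.36. Slide block: Penk −0.0666, Cck 0.0452, Tac1 −0.0220, Cartpt −0.0285. Slide block without OV replicate 3: Gper1 0.045, Avpr1a −0.18, Penk −0.14, Cck 0.0590, Cartpt −0.13, Agtr1a −0.22. Replicate block: Crh −0.00662, Penk −0.0729, Tac1 −0.0437.

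Ranges over leaving out 1 array, low to high, for genes that turned: Esr1 −0.28 to 0.0145, Gper1 −0.30 to 0.0399, Avpr1a −0.24 to 0.27, Crh −0.0384 to 0.11, Crhr1 −0.0727 to 0.0251, Npy −0.0113 to 0.13, Penk −0.0951 to 0.12, Cck −0.12 to 0.0228, Tac1 −0.0578 to 0.23, Cartpt −0.0908 to 0.15, Trh −0.13 to 0.44, Agtr1a −0.18 to 0.34.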

Other observations

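The genes named next were picked after results were seen, and so were the tests of the hypotheses that follow. The authors' own values call 32 named genes, 13 higher and 19 lower in OV+E2. All 32 have the same direction in the scanner values and without OV replicate 3, which is no separate check, as the other arrays are shared. With slide as a block on the authors' values 7 of the 32 pass, among them Cd79a and Fcrl2 but none of the others named here. In the authors' values without OV replicate 3 the number is 0. In the authors' values on all arrays the B-cell gene Cd79a rose by 1.56 (SE 0.20) and Fcrl2 fell by 1.12 (SE 0.09). The T-box gene Tbx3 fell by 1.03 (SE 0.14) and Gpr17, a receptor of differentiating oligodendrocytes, fell by 0.42 (SE 0.06). The growth factor receptor gene Igf1r rose by 0.38 (SE 0.05), as did Cebpb (0.41, SE 0.06) and Lrg1 (0.38, SE 0.06). The interferon-induced Ifi27 fell by 0.51 (SE 0.07). The serine protease gene Htra1 rose by 0.64 (SE 0.10). In the scanner values Cebpb was at +0.17 and Igf1r at +0.26.

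Region markers varied between single rats. The thalamus score was 0.21 in OV+E2 replicate 1 and 0.76 in OV+E2 replicate 2, against −0.34 to −0.20 in the other 3 OV+E2 rats. The choroid plexus score was −1.20 in OV replicate 2 and 1.34 in OV+E2 replicate 2.

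Lower interferon and antigen presentation genes may reflect fewer or less active microglia and blood cells in estradiol-treated rats, as blood markers had a median of −0.206 and microglia markers −0.246. Counts of Aif1-positive cells with Irf7 in the same sections, and RNA from perfused brains, would separate cell number from gene expression per cell.

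Estradiol could lower Avp and Oxt in cells of the amygdala itself, or the OV+E2 dissections could hold less hypothalamus. The median of −0.0380 over the other hypothalamus markers leaves both open. In situ hybridisation of Avp in the medial amygdala and in the paraventricular nucleus of the same rats would show where it fell. Estradiol as the cause was not tested against other differences between the groups.

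The higher thalamus markers may come from the dissection of OV+E2 replicates 1 and 2. Without either of them the call was lost (adjusted p = 0.102 and 0.265) and the median of 0.34 became 0.28 and 0.17. Without single OV arrays the call was lost too (0.0654 to 0.169), while the median stayed at 0.29 to 0.41. Within slide 2, which holds neither of these 2 rats, the median was −0.04. Whether dissection or treatment raised the markers was not tested. Fresh punches with Slc17a6 and Rora measured by PCR would test that. A second hybridisation of the RNA of OV replicate 3 would settle whether its file or the authors' column, which correlate at 0.939, represents that rat.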
